A study of Arabidopsis thaliana with 26 samples.

How the data were processed

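Gene expression was measured in whole 7-day-old seedlings of Arabidopsis thaliana (described in the labels as de-etiolated, Col background, seed stock N6159) with Affymetrix ATH1 arrays, which carry probe sets of short oligonucleotides and are hybridised with biotin-labelled RNA, 1 sample per array. The genotype of the stock is not given in the sources used here, so the plants cannot be taken for wild type; what a response to a precursor means depends on it. The 26 arrays fell into 13 groups of 2: a mock treatment and 12 treatments of 3 h with a brassinosteroid or a precursor. Campestanol was given at 10 µM, castasterone at 100 nM, brassinolide at 10 nM, and each of the other 9 compounds at 1 µM. The arrays of a group carried the letters A and B in the labels. Nothing in the labels says that A and B are separate cultures, so p-values measure only the spread between these arrays, which may be technical.

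The deposited values are probe set intensities on a linear scale, computed by the authors with MAS5 per the submitters' processing notes; the version, the parameters and the detection calls are not given in the sources used here. The 2 to 98% trimmed mean of the deposited intensities was close to 100 on every array (median over arrays 99.97), so the arrays had been scaled to a common mean and no further normalization was applied. Array medians lay between 33.9 and 41.0. Pearson correlations between the log2 values of the 2 arrays of a group, taken across probe sets, lay between 0.948 and 0.975 (median 0.967). Arrays of different groups with the same letter correlated more closely, with a median of 0.973. No pair of arrays held identical values.

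Of 22810 probe sets, 64 controls were left out, and the 17608 with a mean intensity of at least 10.0 over all arrays were tested. A platform table named exactly 1 gene for 13513 probe sets, several genes for 503 and none for 8730. Of the probe sets naming 1 gene, 13436 were matched to a RefSeq gene table (assembly TAIR10.1). That table supplied symbols and the locus names by which the planned gene lists and index markers were matched to probe sets. Among those tested, 9861 named 1 gene. Many well-known genes therefore have no named probe set and were not analysed here.

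Intensities were transformed as log2(value + 5), and fold changes are on that scale, which understates the change of dim probe sets. limma 3.58.1 in R 4.3.3 was fitted to all 26 arrays with 1 coefficient per group and an intensity trend in eBayes, so that 13 groups shared an estimate of the spread with 13 residual degrees of freedom. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05. Each compound was compared with mock. Pairs at 1 µM that differ in the C-6 ketone, their average, successive compounds of each branch, castasterone with 6-deoxocastasterone and brassinolide with castasterone were also compared, and probe sets that differed among the 13 groups were counted. Precision is limited by the number of arrays, 2 per group, and by the difference between the letters, which stays in the spread of this fit. On simulated data with 200 changed probe sets among 17608, a comparison like that of brassinolide with mock recovered 49% of changes of 1 on the log2 scale and 94% of changes of 2, with 4 false calls. A comparison like that of typhasterol with 6-deoxotyphasterol recovered 44% and 91%, with 8 false calls, and the average over the C-6 pairs recovered 92% and 100%, with 7 false calls. The simulated change was the same in every C-6 pair, so the last 2 shares do not hold for a change confined to some pairs. Arrays were drawn independently, without a shared difference between the letters.

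The comparisons, tests, thresholds, 27 gene lists and the rule for naming genes were chosen before the data were examined. By that rule the named genes are the 12 largest rises and the 12 largest falls past the threshold for brassinolide and castasterone and the 4 of each for every other comparison, among probe sets naming exactly 1 gene whose arrays did not overlap between the groups. List members may be named as examples when a list is described. Of the 245 genes in the 27 lists, 30 had a named probe set, and only 3 lists kept at least 3 tested members: xyloglucan endotransglucosylase/hydrolases (XTH), expansins, and Aux/IAA and GH3 genes. A further 22 lists were therefore drawn from the genes that the annotation names, after the annotation had been seen and before any comparison was run, and 21 of them could be tested. Lists were tested with camera of limma at an inter-gene correlation of 0.01, with an estimated correlation as a check and fry beside it. Adjustment was over all lists and comparisons of a family (12 against mock, 5 for C-6, 7 steps).

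A response index had been planned from genes induced and genes repressed by brassinosteroids. None of the 10 repressed markers had a named probe set and 2 of the 16 induced ones did, EXPA8 and ARL, so the index is the mean of these 2. A signature score was added after the data were seen: the mean log2 value of the 454 probe sets called for brassinolide against mock, with lower-called ones counted negatively. Its members were chosen by their difference between the brassinolide and mock arrays, so the brassinolide and mock scores are selected on. The other arrays entered the choice through the estimate of the spread, to which all 26 contribute, and through the mean intensity used by the filter and the trend, but not through their differences from mock. Scores were compared with 95% intervals from the spread pooled over 13 groups. A two-sided exact permutation test over 1296 relabellings within the 4 pairs served for the average C-6 effect. Permutation tests with 100000 resamples served for the trend over pathway position (two-sided) and, on the index, for differences among groups. A single pair of groups of 2 has no useful exact test, so such pairs have intervals and no p.

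Comparisons against mock share 2 control arrays. Correlations and overlaps are given beside 50 simulations of unchanged groups and beside the overlap of independent lists. The 2 controls were not split between compounds, so part of any excess may come from sharing them. The simulations drew each array independently, with a spread that holds the difference between the letters A and B. Each group has 1 array of each letter, so the simulated correlation and covariance may be too high. Alternatives tried were quantile normalization, median centring, smaller and larger pseudocounts (1.25 and 20), no filter and a stricter filter (mean of at least 50.0), the replicate letter as a block, eBayes without the trend, fits to 4 arrays alone for brassinolide and castasterone, and leaving out each array in turn, which assumes that the lone remaining array varies like the other groups. Figures were drawn with matplotlib.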

Results

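The series comprised 26 ATH1 arrays of Arabidopsis seedlings: 2 mock-treated and 2 for each of 12 steroids applied for 3 h. The compounds lie along the route from campestanol to brassinolide, the most active brassinosteroid, which promotes cell elongation. They form a 6-oxo series (cathasterone, teasterone, 3-dehydroteasterone, typhasterol, castasterone) and a 6-deoxo series of the same steps without the C-6 ketone. The comparisons ask how far each intermediate evokes the brassinolide response, and what the C-6 ketone and each step add to it. Values are MAS5 intensities, given as mean ± SD with n = 2 unless stated otherwise. Changes of a gene on the log2 scale are given ± SE.

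Brassinolide at 10 nM raised several genes whose products act on the cell wall. EXO (EXORDIUM), a brassinosteroid-responsive gene, stood at 170 ± 50.6 in mock and 1160 ± 103 after brassinolide, a log2 change of 2.76 ± 0.30 (SE). The expansin-like genes EXLA1 and EXLA2 rose by 3.05 ± 0.46 and 2.88 ± 0.29, EXLA2 from 16.9 ± 8.04 to 151 ± 6.64. XTH33, which encodes an enzyme that cuts and rejoins xyloglucan, rose from 25.6 ± 1.45 to 214 ± 4.46 (log2 change 2.84 ± 0.31), and the pectin methylesterase gene ATPMEPCRB rose by 2.44 ± 0.37. Among probe sets naming 1 gene, the largest falls were those of AT5G01740, by a log2 change of -3.69 ± 0.36, and AT5G57785, from 519 ± 62.3 to 37.3 ± 8.56 (-3.64 ± 0.30). Unnamed probe sets moved further, with log2 changes of 4.44 and 4.26 upward and -4.46 downward. The rule also took AT1G29660 (3.69), XTH19 (8.60-fold), AT3G50560 (2.96), XTH18 (2.67), AT5G45670 (2.64), AT5G24570 (2.45) and AT2G31730 (2.32) among the rises. Among the falls it took P1R1 (-1.54), AT2G03750 (-1.39), AT3G23550 (-1.90), AT5G02540 (-1.72), AT1G17230 (-1.59), AT2G29660 (-1.56), AT1G32190 (-1.48), AT1G66890 (-1.47), AT4G16146 (-1.39) and AT5G58660 (-1.33). In all, limma called 454 of 17608 probe sets, 356 higher and 98 lower, of which 230 and 66 changed at least 2-fold, and 205 name 1 gene. The count fell to 229 and 180 without the A and B array of brassinolide and to 204 without mock array B. Of the 12 named rises 10 kept their calls without each of the 4 arrays, as did 4 of the 12 falls: AT5G01740, AT5G57785, P1R1 and AT2G03750. AT2G29660 was not called with quantile normalization, median centring, the smaller pseudocount, no filter or eBayes without the trend.

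The XTH list, fixed in advance, held 5 tested members, of which XTH19, XTH33, XTH18 and XTH16 rose after brassinolide, while XTH20 stood at -0.23. The same 4 members were called when adjusted over the list alone. The list's median log2 change was 2.67 (camera adjusted p = 2.79e-09, and 0.00684 with an estimated correlation). Of the 3 tested expansins, EXPA8 rose (1.98 ± 0.23), over all probe sets and adjusted over the list alone. The expansin median was 0.16, with camera adjusted p = 0.0353 and adjusted p = 0.0669 with an estimated correlation. None of the Aux/IAA and GH3 members, auxin-response genes, was called for any compound, and the list's lowest adjusted p against mock was 0.498. After brassinolide limma called 0 of 7 root markers (list median -0.20, adjusted p = 0.791) and 0 of 4 seed markers (median -0.26, adjusted p = 0.707), lists too short to rule out a shift.

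Castasterone at 100 nM moved the same genes by similar amounts. EXO reached 1548 ± 493 (log2 change 3.14 ± 0.30), EXLA1 rose by 3.12, XTH19 by 3.05, EXLA2 by 2.92, XTH33 by 2.91, AT3G50560 by 2.89 and ATPMEPCRB by 2.29. AT5G01740 (-3.58), AT5G57785 (-3.57), P1R1 (-1.76), AT4G16146 (-1.45) and AT2G03750 (-1.41) were lower. The XTH list shifted by a median of 2.65 with 4 of 5 members higher (adjusted p = 1.49e-08, and 0.00684 with an estimated correlation). The rule further took AT1G29660 (3.47), XTH18 (2.65), AT3G55840 (2.46), AT5G45670 (2.43) and AT5G24570 (2.36) among the rises. Further falls were AT3G23550 (-1.74), AT1G32190 (-1.71), AT5G22580 (-1.62), AT1G69730 (-1.51), AT1G66890 (-1.50), AT5G02540 (-1.47) and AT4G25780 (-1.40). In all 419 probe sets were called, 314 higher and 105 lower. The count fell to 190 and 273 without castasterone array A or B and to 192 without mock array B, and was 151 when only the 4 arrays compared entered the fit. Without each of the 4 arrays in turn, 9 of the 12 named rises and 5 of the 12 falls kept their calls, and AT3G23550 was not called with no filter or with the smaller pseudocount.

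Brassinolide and castasterone were compared directly, though at doses of 10 nM and 100 nM. limma called 0 probe sets between them, with 333 at an unadjusted p under 0.05. EXO differed by -0.38 (95% interval -1.01 to 0.25), XTH33 by -0.06 (-0.72 to 0.60) and AT5G57785 by -0.08 (-0.71 to 0.56). Against mock, 275 probe sets were called higher and 69 lower for both compounds, where independent lists would share 6.35 and 0.584 and simulated unchanged groups shared at most 1. Their log2 changes correlated at 0.802 across probe sets, against 0.501 for simulated groups that share the controls, and their covariance was 0.130 against 0.0451, a difference of 0.0852. Probe sets are not independent replicates, and part of the excess may come from the shared mock arrays.

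Among the compounds given at 1 µM, the later intermediates changed the same leading genes. EXO rose by 1.90 after 6-deoxoteasterone, 2.45 after teasterone, 2.51 after 3-dehydro-6-deoxoteasterone, 2.81 after 3-dehydroteasterone, 2.87 after typhasterol and 2.64 after 6-deoxocastasterone, and it was also higher after 6-deoxotyphasterol (adjusted p = 0.00259). AT5G57785 was lower after each of the 7, with log2 changes of -2.35 after teasterone, -2.59 after 3-dehydro-6-deoxoteasterone, -2.23 after 6-deoxotyphasterol, -3.83 after typhasterol and -3.80 after 6-deoxocastasterone. Counting castasterone and brassinolide, 17 probe sets changed in a single direction for all 9 of these compounds. The named ones are EXO, AT4G27280, AT2G47440 and AT3G06770, which were higher, and AT5G01740, AT5G57785 and P1R1, which were lower. Over all compounds, 600 probe sets were called at least once, 95 for 6 or more compounds, and 0 in opposite directions by any 2 compounds at an adjusted p under 0.05 in limma. The shared mock arrays favour calls in the same direction, and these counts have no simulated counterpart.

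The number of called probe sets differed widely among these compounds. It was 343 for 6-deoxocastasterone (276 higher, 67 lower), 312 for typhasterol (233 and 79), 250 for 3-dehydroteasterone (188 and 62), 98 for 3-dehydro-6-deoxoteasterone (75 and 23), 62 for teasterone (49 and 13), 34 for 6-deoxotyphasterol (24 and 10, P1R1 among the lower but not called under 5 of the alternatives) and 29 for 6-deoxoteasterone (14 and 15). The XTH list was called for each of the 7, with adjusted p between 6.39e-09 and 3.27e-05 and at most 0.0212 with an estimated correlation. XTH19, XTH33, XTH18 and XTH16 rose after 6-deoxocastasterone, typhasterol and 3-dehydroteasterone. Only XTH33 was called among the 5 after teasterone and 3-dehydro-6-deoxoteasterone, and 0 after 6-deoxoteasterone and 6-deoxotyphasterol by limma, which had 690 and 757 probe sets at an unadjusted p under 0.05. Adjusted over the list alone, 4 members were higher for teasterone and 3-dehydro-6-deoxoteasterone, 3 for 6-deoxoteasterone and 2 for 6-deoxotyphasterol. EXPA8 was higher for all of these compounds except 6-deoxoteasterone (0.78 ± 0.23, adjusted p = 0.515), where it passed when adjusted over the list alone. The expansin list was called for teasterone (adjusted p = 0.00150, and 0.0155 with an estimated correlation), 3-dehydro-6-deoxoteasterone (0.00470 and 0.0212) and 6-deoxotyphasterol (0.00224 and 0.0161), as well as for cathasterone, 6-deoxocastasterone and castasterone (0.0353 each), where the estimated correlation gave adjusted p = 0.0669. For 3-dehydroteasterone and typhasterol its median was -0.08 and -0.03 while its mean and test pointed up, at adjusted p = 0.0509 and 0.0739. Other genes taken by the rule were AT5G44680 (1.11) and AT1G76240 (-1.25) for 6-deoxoteasterone, AT5G57760 (-1.87) for 3-dehydro-6-deoxoteasterone, AT5G22600 (-2.19) for 3-dehydroteasterone, AT2G18420 (-1.70) for 6-deoxotyphasterol (not called with the larger pseudocount), AT3G04010 (-1.67) for typhasterol and AT1G66890 (-1.60) for 6-deoxocastasterone.

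**Figure D1:**
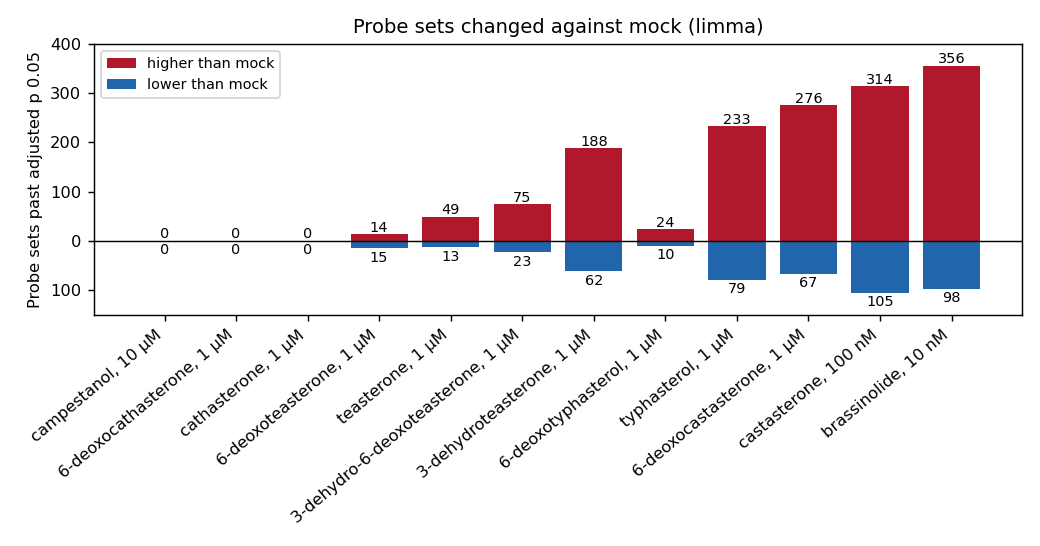
Probe sets past an adjusted p of 0.05 in limma for each compound against mock, with those higher above 0 and those lower below 0 and the dose beside each name. Counts run from 0 for campestanol, 6-deoxocathasterone and cathasterone to 356 higher and 98 lower for brassinolide.

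These counts rested on 2 arrays a side. Leaving out any of the 4 arrays lowered the count in all 36 fits of the 9 compounds, by over 1.5 times in 31, and ended it in none of them. With mock array A or B left out, the counts were 225 and 138 for 6-deoxocastasterone, 194 and 152 for typhasterol, 131 and 78 for 3-dehydroteasterone, 41 and 36 for 3-dehydro-6-deoxoteasterone, 38 and 23 for teasterone, 17 and 14 for 6-deoxotyphasterol and 11 and 14 for 6-deoxoteasterone. With the compound's own array A or B left out they were, in the same order, 180 and 263, 130 and 163, 122 and 87, 51 and 38, 50 and 16, 6 and 10, and 24 and 5. EXO and AT5G01740 kept their calls without each array for teasterone, 3-dehydro-6-deoxoteasterone, 3-dehydroteasterone, typhasterol and 6-deoxocastasterone, but for 6-deoxoteasterone none of the 8 named genes did. For 6-deoxotyphasterol 0 of the 4 named rises did, and EXO was not called without mock array B or 6-deoxotyphasterol array A; of the 4 falls only AT5G01740 did.

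Campestanol, 6-deoxocathasterone and cathasterone had no called probe set in limma, with 272, 574 and 563 at an unadjusted p under 0.05. The log2 change of EXO against mock was 0.26 ± 0.30 (SE) after campestanol at 10 µM and 1.17 ± 0.30 after 6-deoxocathasterone. After cathasterone it was 1.64 ± 0.30 (adjusted p = 0.0817 in limma). For AT5G01740 the log2 changes were 0.31 ± 0.36, -1.50 ± 0.36 and -2.20 ± 0.36 in the same order (adjusted p = 0.0563 for cathasterone in limma). The XTH list had medians of 0.09, 0.27 and 0.35, with adjusted p = 0.895, 0.584 and 0.0509. Cathasterone gave 6 calls with quantile normalization, 4 with median centring or the larger pseudocount, and 3 with the stricter filter. 6-deoxocathasterone gave 1 with quantile normalization or the larger pseudocount. Blocking the replicate letter, described further on, gave more calls than these for both compounds. Without the B array of campestanol or of 6-deoxocathasterone, 7 and 4 probe sets were called.

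**Figure D2:**
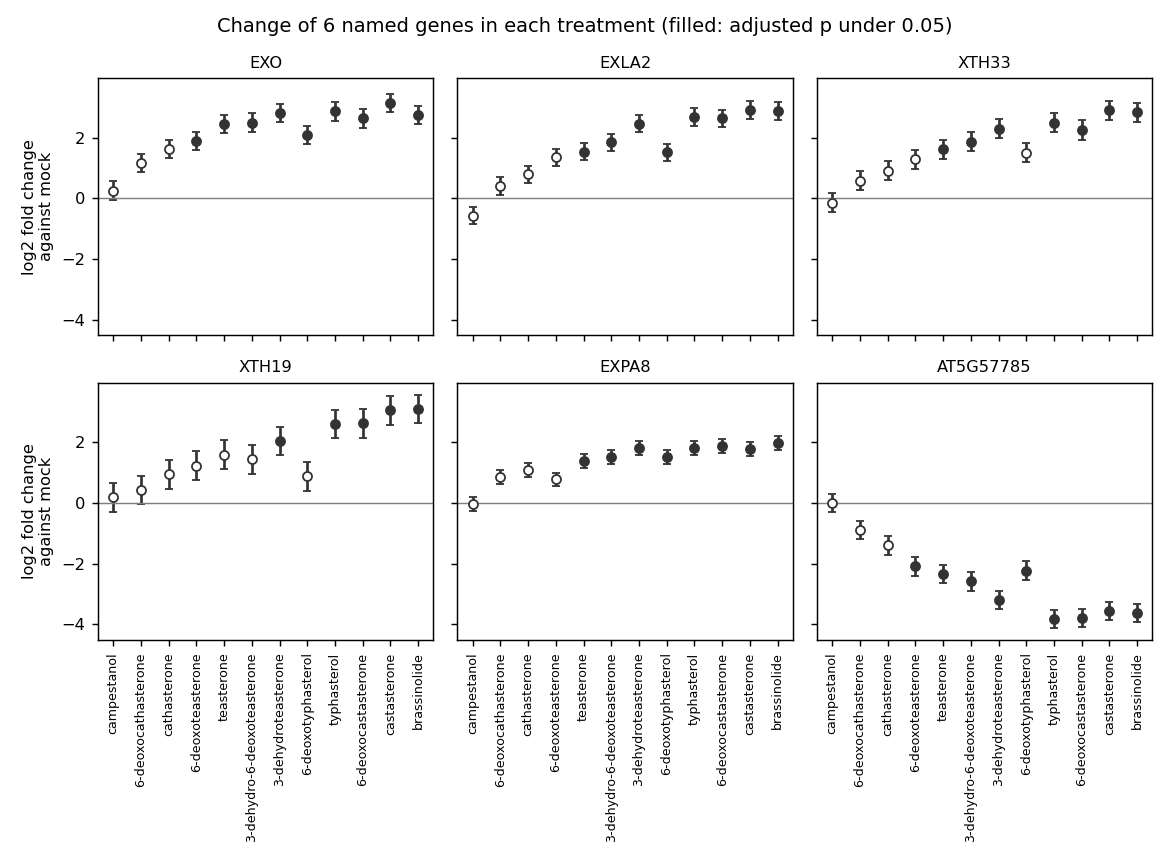
Log2 fold change against mock, with bars of 1 standard error, for 6 genes after each of the 12 compounds; filled points have an adjusted p under 0.05. EXO, EXLA2, XTH33, XTH19 and EXPA8 lie highest for the late compounds, and AT5G57785 reaches -3.83 after typhasterol.

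The signature score condensed the response into a value per array. It was 3.37 ± 0.06 in mock and 3.43 ± 0.02 after campestanol. Above campestanol it rose by 0.28 for 6-deoxocathasterone (95% interval 0.09 to 0.46), 0.41 for cathasterone (0.22 to 0.59), 0.54 for 6-deoxoteasterone, 0.65 for 6-deoxotyphasterol, 0.74 for teasterone, 0.81 for 3-dehydro-6-deoxoteasterone, 1.00 for 3-dehydroteasterone, 1.14 for typhasterol and 1.22 for castasterone. Relative to castasterone at 100 nM, 6-deoxocathasterone at 1 µM reached 22.8% of the rise and cathasterone 33.5%, although neither had a called probe set, and 6-deoxocastasterone reached 90.3%. Brassinolide, on which the score was built, stood 1.28 above campestanol. On the index of EXPA8 and ARL the 13 groups differed (permutation p = 4e-05). ARL itself was called for no compound by limma (0.33 after brassinolide).

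**Figure D3:**
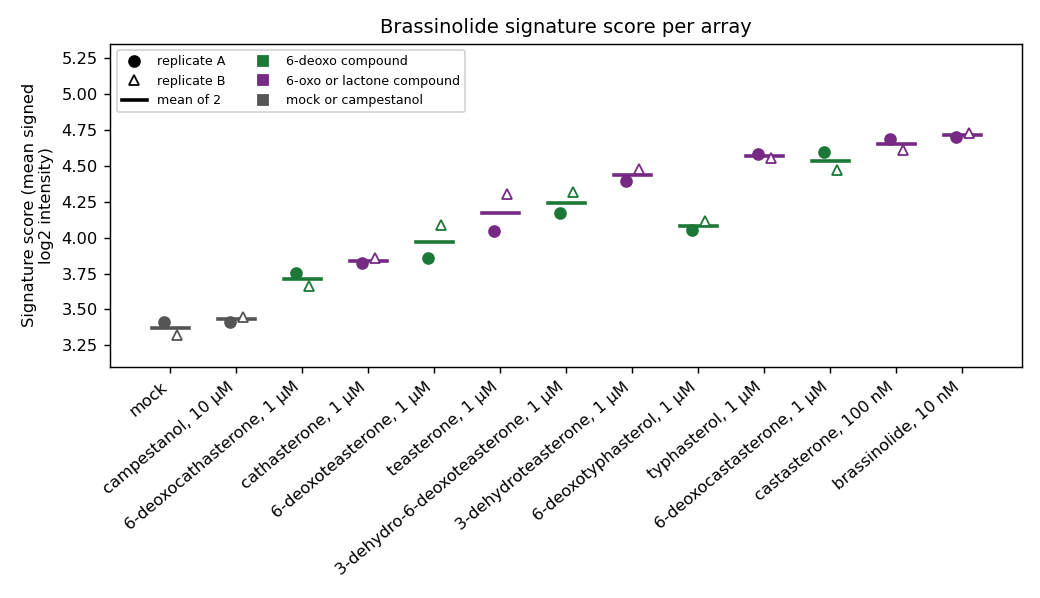
Brassinolide signature score of each of the 26 arrays, as the mean signed log2 intensity of 454 probe sets, with circles and triangles for replicates A and B and a bar at the mean of 2. Scores run from 3.37 in mock to 4.71 after brassinolide, and typhasterol (4.57) lies well above 6-deoxotyphasterol (4.08).

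The effect of the C-6 ketone was compared in 4 pairs at 1 µM. AT5G57785 was lower after typhasterol than after 6-deoxotyphasterol by a log2 difference of -1.59 (95% interval -2.23 to -0.96), and XTH19, XTH18 and EXLA2 differed by 1.73 (0.75 to 2.72), 1.69 (0.59 to 2.79) and 1.17 (0.56 to 1.77). None of these passed adjustment over all probe sets (adjusted p of 0.272 or more). Averaged over the 4 pairs, EXO stood 0.52 higher (0.20 to 0.84), EXLA2 0.59 (0.29 to 0.89) and EXPA8 0.37 (0.12 to 0.61) with the ketone. The naming rule took no gene in these comparisons, so these are examples with unadjusted intervals. Not every leading gene moved so: against mock, P1R1 fell less with the ketone for teasterone (-1.25 against -1.53) and 3-dehydroteasterone (-1.73 against -2.03). It fell more for typhasterol (-1.76 against -1.22). limma called 0 probe sets for the cathasterone, teasterone, 3-dehydroteasterone and typhasterol pairs, with 477, 500, 693 and 633 at an unadjusted p under 0.05, and 0 for the average, with 611. It also called 0 for a C-6 effect that differed among the pairs, with 466. These fits did not block the replicate letter. With that block, an alternative described further on, the typhasterol pair and the average did have called probe sets.

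The XTH list was higher with the ketone in the typhasterol pair (median 1.00) and on average (median 0.52). Each had camera adjusted p = 5.73e-05, and 0.0481 with an estimated correlation. By fry, 0 of the 15 C-6 tests of the 3 fixed lists were called, so fry did not call this list. Over all probe sets 0 of its 5 members passed in limma; adjusted over the list alone, 4 were higher in the typhasterol pair and 3 on average. In the cathasterone, teasterone and 3-dehydroteasterone pairs its medians were 0.34, 0.33 and 0.56, with adjusted p = 0.265, 0.495 and 0.121. On the signature score the ketone added 0.13 for cathasterone (95% interval -0.06 to 0.32), 0.20 for teasterone (0.02 to 0.39), 0.19 for 3-dehydroteasterone (0.01 to 0.38) and 0.48 for typhasterol (0.30 to 0.67). The arrays of the teasterone pair overlapped, with teasterone array A at 4.05 and 6-deoxoteasterone array B at 4.09. Their SDs of 0.18 and 0.16 exceeded the pooled SD of 0.09 behind the interval. The average effect of the ketone was 0.25, positive in 4 of 4 pairs (exact permutation p = 0.00309). For the index of EXPA8 and ARL it was 0.42 (exact permutation p = 0.00154, the smallest the 1296 relabellings can give), also positive in 4 of 4. On the score the typhasterol pair had the largest effect, so unadjusted intervals that set it against the other pairs exclude 0 too easily. The typhasterol pair differed from the cathasterone pair by 0.35 (0.09 to 0.62), from the teasterone pair by 0.28 (0.02 to 0.55) and from the 3-dehydroteasterone pair by 0.29 (0.03 to 0.56). On the index of EXPA8 and ARL these differences were 0.34 (-0.16 to 0.84), -0.04 (-0.55 to 0.46) and -0.02 (-0.52 to 0.49), so the typhasterol pair did not stand out there, and the teasterone pair had the largest effect (0.53). Permutation tests of unequal effects over all 4 pairs gave p = 0.142 on the score and 0.365 on the index.

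Single steps were compared at 1 µM within each series. AT5G57785 was lower after teasterone than after cathasterone, which lacks the C-23 hydroxyl, by -0.95 (95% interval -1.58 to -0.32), and EXO was higher by 0.81 (0.18 to 1.44). In the 6-deoxo series the same hydroxyl went with -1.20 (-1.83 to -0.56) for AT5G57785 and 0.73 (0.09 to 1.36) for EXO. From 6-deoxotyphasterol to 6-deoxocastasterone, which carries an added 2α-hydroxyl, AT5G57785 differed by -1.56 (-2.20 to -0.93) and XTH19 by 1.75 (0.76 to 2.73). None of these passed adjustment over all probe sets (adjusted p of 0.205 or more), so the naming rule did not take them. In the fit without the replicate block, the 1 probe set called was that of AT1G19020. It stood at 208 ± 42.6 after 6-deoxocastasterone and 59.9 ± 0.46 after 6-deoxotyphasterol (log2 difference 1.70 ± 0.23, adjusted p = 0.0117 in limma). The call was lost without 6-deoxocastasterone array B or either 6-deoxotyphasterol array. Without the replicate block limma called 0 probe sets in the other steps. With that block, an alternative described further on, 6-deoxocastasterone against 6-deoxotyphasterol had many more called probe sets. The step from 6-deoxocathasterone to 6-deoxoteasterone then had some as well. At an unadjusted p under 0.05 there were 422 for teasterone against cathasterone, 404 for 3-dehydroteasterone against teasterone and 293 for typhasterol against 3-dehydroteasterone. In the 6-deoxo series there were 995, 579 and 623 for the corresponding steps. The XTH list was called for the C-23 hydroxyl in both series (medians 0.65 and 0.59), for 3-dehydroteasterone against teasterone (0.67) and for 6-deoxocastasterone against 6-deoxotyphasterol (0.94), with adjusted p between 4.24e-04 and 0.00214. With an estimated correlation the adjusted p was 0.120 to 0.124, so none of the 4 list calls was kept. By fry, 0 of the 21 step tests of the fixed lists were called. Adjusted over the list alone, 4 members were higher for 6-deoxocastasterone against 6-deoxotyphasterol, 1 for 3-dehydroteasterone against teasterone and 0 for the C-23 hydroxyl (limma).

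The signature score rose with the C-23 hydroxyl by 0.33 (95% interval 0.15 to 0.52) in the 6-oxo and 0.26 (0.08 to 0.45) in the 6-deoxo series. Oxidation of the 3β-hydroxyl to a ketone went with 0.26 (0.07 to 0.45) and 0.27 (0.08 to 0.45). Reduction to the 3α-hydroxyl went with 0.13 (-0.05 to 0.32) from 3-dehydroteasterone to typhasterol, and with -0.16 (-0.34 to 0.03) from 3-dehydro-6-deoxoteasterone to 6-deoxotyphasterol. The 2α-hydroxyl of 6-deoxocastasterone went with 0.45 (0.26 to 0.63). Over the 4 positions the score rose by 0.19 per position (permutation p = 1.4e-04), 0.24 in the 6-oxo and 0.14 in the 6-deoxo series. For the index of EXPA8 and ARL the trend was 0.18 (permutation p = 3.5e-04). Both tests relabelled single arrays within a series, so their p also reflects differences among compounds and does not test their order alone.

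Castasterone at 100 nM and 6-deoxocastasterone at 1 µM differed in dose as well as in the C-6 ketone. EXO stood at 1548 ± 493 and 1092 ± 327, XTH33 at 225 ± 23.1 and 144 ± 43.5, and AT5G57785 at 40.1 ± 13.1 and 33.8 ± 13.2. The score difference was 0.12 (95% interval -0.07 to 0.30). The 1 probe set called was again that of AT1G19020, lower after castasterone (65.2 ± 1.01) by a log2 difference of -1.59 ± 0.23 (adjusted p = 0.0304), with 358 probe sets at an unadjusted p under 0.05. The call was lost with quantile normalization, median centring or eBayes without the trend (adjusted p = 0.0539, 0.0607 and 0.0579), and without 6-deoxocastasterone array B or either castasterone array.

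**Figure D4:**
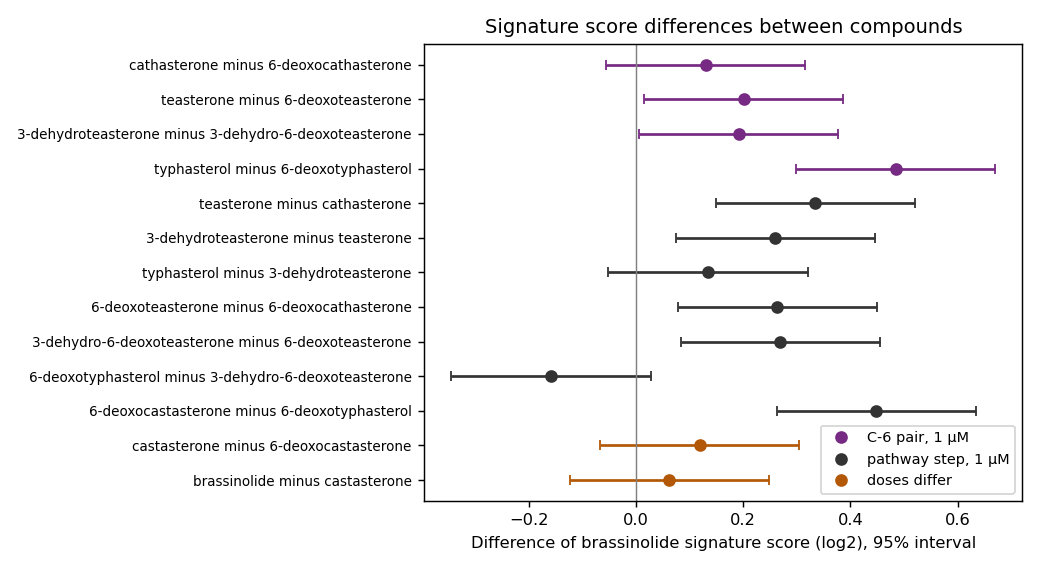
Differences of the brassinolide signature score between compounds with 95% intervals, for C-6 pairs and pathway steps at 1 µM and for 2 comparisons at unequal doses. Intervals exclude 0 for 3 of the 4 C-6 pairs, although the arrays of the teasterone pair overlap. The widest gap is 0.48 for typhasterol against 6-deoxotyphasterol.

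Across all groups, limma called 378 probe sets that differed among the 13 groups, 168 of them naming 1 gene. Relative to brassinolide, the 454 called probe sets moved in the direction of brassinolide in 436 cases after cathasterone and 393 after 6-deoxocathasterone, against 282 after campestanol. All of these comparisons share the mock arrays on which the probe sets were selected, so such counts are raised even without a response. The covariance is taken over all probe sets. The covariance with the brassinolide changes was 0.0264 for campestanol, 0.0507 for 6-deoxocathasterone and 0.0614 for cathasterone, against 0.0451 in simulated unchanged groups. Campestanol lay below the simulated value. The simulated spread holds the difference between the letters, so 0.0451 is not an exact baseline.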

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

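The lists drawn from the annotation, the signature score and its castasterone counterpart were added after the plan was fixed and are said so here; the other alternatives were chosen before the data were examined. Counts for brassinolide, castasterone, 6-deoxocastasterone, typhasterol, 3-dehydroteasterone, 3-dehydro-6-deoxoteasterone, teasterone, 6-deoxotyphasterol and 6-deoxoteasterone against mock stayed within 1.5 times under quantile normalization, median centring, both pseudocounts, both filter settings and eBayes without the trend. Of the brassinolide calls reported, 424 were shared by the 464 of quantile normalization, 386 by the 410 of median centring, 453 by the 456 of the smaller pseudocount and 395 by the 397 without the trend.

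Some small counts changed, and the cause was not tested. For 6-deoxocathasterone quantile normalization and the larger pseudocount gave 1 each; for cathasterone quantile normalization gave 6, median centring 4, the larger pseudocount 4 and the stricter filter 3. For castasterone against 6-deoxocastasterone quantile normalization, median centring and eBayes without the trend gave 0; for 6-deoxocastasterone against 6-deoxotyphasterol eBayes without the trend gave 2. With only the 4 arrays compared, which leaves 2 residual degrees of freedom, castasterone gave 151. Of the gene list shifts 22 were called, and 14 stayed with an estimated correlation. The added lists gave 53 over 504 tests, of which 13 stayed with an estimated correlation (all against mock). By fry, 17 of the 72 fixed-list tests and 25 of the 504 added-list tests were called, all against mock.

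The replicate letter as a block was to enter the comparisons only if the deviations of the A arrays correlated above 0.1 in every pair of groups. They did in 76 of 78 pairs (lowest -0.02, median 0.32), so it stayed an alternative. With it the counts rose to 6 for 6-deoxocathasterone, 20 for cathasterone, 79 for 6-deoxoteasterone, 184 for teasterone, 270 for 3-dehydro-6-deoxoteasterone, 516 for 3-dehydroteasterone, 105 for 6-deoxotyphasterol, 709 for typhasterol, 804 for 6-deoxocastasterone, 937 for castasterone and 917 for brassinolide. It gave 18 for typhasterol against 6-deoxotyphasterol, 10 for the average C-6 effect, 3 for 6-deoxoteasterone against 6-deoxocathasterone, 41 for 6-deoxocastasterone against 6-deoxotyphasterol and 883 among the 13 groups. For 25 of 26 arrays, the best-correlated array among those of other groups had the same letter.

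Leaving out 1 array gave 0 to 7 calls for campestanol, 0 to 4 for 6-deoxocathasterone, 5 to 24 for 6-deoxoteasterone, 16 to 50 for teasterone, 36 to 51 for 3-dehydro-6-deoxoteasterone, 78 to 131 for 3-dehydroteasterone, 6 to 17 for 6-deoxotyphasterol, 130 to 194 for typhasterol, 138 to 263 for 6-deoxocastasterone, 190 to 293 for castasterone and 180 to 310 for brassinolide. It gave 0 to 1 for 6-deoxoteasterone against 6-deoxocathasterone, 0 to 5 for 6-deoxocastasterone against 6-deoxotyphasterol, 0 to 3 for castasterone against 6-deoxocastasterone and 300 to 389 among the 13 groups. Of 105 values of named genes, 3 lost their call with quantile normalization, 3 with median centring, 3 with the smaller pseudocount, 2 with the larger, 3 with no filter and 6 without the trend, and 0 changed sign; leaving out 1 array ended 140 of 420 calls. Fewer arrays are the construction of these fits.

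The tests of the index, and the C-6 and trend tests of the signature score, kept their side of 0.05 under all alternatives run. Leaving out 1 array, the average C-6 effect on the signature score ranged from 0.22 to 0.28 (exact permutation p 0.00309 to 0.0108) and its trend from 0.18 to 0.22. With the castasterone signature of 419 probe sets the average C-6 effect was 0.26. Using induced markers alone gives the same index by construction, and repressed markers alone give no value, since none had a named probe set.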

Other observations

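Chosen only after the results were seen were the signature score, the permutation test of unequal C-6 effects, the tests of the spread between replicates and of fits with equal numbers of arrays for 6-deoxotyphasterol, the share of higher calls by level after campestanol and the other splits of the arrays. The differences of the typhasterol pair from the other C-6 pairs on that score were likewise taken after the results were seen. The lists used here were drawn from the annotation before any comparison was run.

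Further genes changed after brassinolide. RALFL33, which encodes a RALF-like peptide, rose from 166 ± 9.01 to 400.4 ± 74.7 (n = 2; log2 change 1.24 ± 0.22, adjusted p = 0.00237), and the receptor kinase gene THE1 rose from 98.3 ± 19.5 to 239 ± 0.41 (1.25 ± 0.18). BZIP60, a transcription factor gene of the unfolded protein response, rose by 0.74 ± 0.15 and the calmodulin-like gene CML42 by 0.66 ± 0.16. IAGLU, which encodes an auxin glucosyltransferase, was lower (-1.22 ± 0.26, adjusted p = 0.0114). These genes were singled out after their values were seen.

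Of the 21 added lists, 12 had no call against mock. After brassinolide the brassinosteroid-linked list had 3 of 8 members higher (EXO, EXPA8, THE1; median 0.40, adjusted p = 1.98e-04, and 0.0847 with an estimated correlation). The XTH genes had 4 of 8 higher (median 1.16, 1.10e-05 and 0.0279), and expansins with expansin-like genes 3 of 15 (median 0.16, 0.0110 and 0.0718). Jasmonate and wounding genes had 1 of 12 (CML42; median 0.54, 0.0155 and 0.283), and RALF-like genes 1 of 6 (median 0.43, 0.0478 and 0.445). All 18 nuclear photosynthesis genes stood below mock with 0 called by limma (median -0.26, 0.0110 and 0.567). All 18 also stood below mock after 6-deoxotyphasterol (median -0.18, adjusted p = 0.0539) and 6-deoxocastasterone (median -0.14, adjusted p = 0.0874), while 10 of the 18 stood above it after castasterone (median 0.08, adjusted p = 0.912). Brassinolide and castasterone were not tested against each other on this list. The CYP71B list was lower after 3-dehydroteasterone than after 3-dehydro-6-deoxoteasterone (median -0.46, adjusted p = 5.21e-04, and 0.240 with an estimated correlation).

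More probe sets were higher than lower after brassinolide (78.4% of 454). The share was 75.2% with quantile normalization and 72.93% with median centring, which argues against scaling of the arrays as the whole cause. Among the 227 called probe sets whose level after campestanol was at least the trimmed mean, 157 were higher (69.16%, 95% binomial interval 62.7 to 75.1, which takes probe sets as independent). The share is smaller than over all called probe sets, so falls lost near the floor of the values may account for part of the excess, and how much stays open.

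6-deoxotyphasterol had fewer called probe sets than 3-dehydro-6-deoxoteasterone, its precursor (34 against 98). Leaving out an array lowers the count of its own compound, so 1 array of each compound was left out together: the count stayed lower in 4 of 4 such fits (5 against 34, 5 against 27, 10 against 34 and 10 against 27), which argues against 1 array deciding it. The index of EXPA8 and ARL went the other way, 0.11 higher after 6-deoxotyphasterol (95% interval -0.25 to 0.46). The interval of the castasterone signature score difference reached 0.026392, so the spread between replicate arrays stays open and may account for the gap. The part of the brassinolide signature made of lower-called probe sets differed by -0.22 (95% interval -0.38 to -0.05) and the part made of higher-called ones by -0.14 (-0.35 to 0.07). No biological explanation was tested.

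Arrays with the letter A separated from those with the letter B on the first principal component (20.4% of the variance), and 6297 probe sets (35.8%) differed between the letters in limma. Ratios of 3′ to 5′ control probe sets moved in the majority direction in as few as 7 of 13 groups for ubiquitin and 8 for GAPDH, but were lower in B in 11 for actin, so RNA length or labelling cannot be told apart from other sources. The root marker list differed by a median of -0.2544 and nuclear photosynthesis genes by -0.26, both lower in B and short of the threshold. The chloroplast-encoded photosynthesis and ATP synthase list had 1 of 43 members higher in B (median -0.36) and the lowest adjusted p of the 21 lists (0.0539 with an estimated correlation). The share of roots and shoots cannot be told apart from other sources either. The labels do not say what the letters stand for.

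For the average C-6 effect, limma without the replicate block called 0 probe sets (611 at an unadjusted p under 0.05). Other splits of the 16 arrays within pairs gave at most 3. Any split reaches a count of 0, as 100 of 100 did, so the splits say nothing about chance here.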
